A study of Mus musculus with 6 samples.

How the data were processed

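Messenger RNA of mixed cortical and hippocampal primary neurons from C57BL/6 mice, collected on day 18 in vitro, was measured in 6 libraries, 3 wild type (WT) and 3 Tlr7-/-. Per the labels, libraries were made with the TruSeq Stranded mRNA kit and sequenced on a NextSeq500. Per the submitters' processing notes the genome build was GRCm38.p6, and HISAT2, featureCounts, edgeR and bcl2fastq are named, with no version given. The notes do not say which of these tools made which table.

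Per the file headers the authors' gene table holds raw total counts per gene, which are whole numbers and were used as the main measurement. The same deposited table holds RPKM values, which the authors scaled by gene length and by a total of mapped reads that is not the sum of the count column. It also holds TPM values, deposited by the authors, which sum to the same total in each library and were not used here beyond a check of the unit. The comparison columns of this table are not used here. A second deposited table holds the authors' edgeR comparison, with log2 fold changes and mean log2 CPM, per the file headers. Its p-value and false discovery rate columns are the authors' own, and the test and normalization behind them are not stated in the labels.

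Total counts were 23272450 to 25696625 per library. A count of 0 allows up to 3 counts at the 95% level, or 0.117 to 0.129 CPM (counts scaled to library size); such limits and the intervals of count ratios cover counting error only. GC content and transcript length came from GENCODE M21, which gave a GC value for 99.9% of genes in the table, and 94.7% of matched genes had the same position.

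Genes were filtered with filterByExpr by genotype, which kept 13947 of 25814 genes and 99.96% of counts. Libraries were scaled by TMM, and genotypes were compared with edgeR 4.0.16 (glmQLFit with robust=TRUE, then the two-sided glmQLFTest) in R 4.3.3, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. No replicate block was used, since the labels name no pairing. A fit with 3 groups, namely WT, Tlr7-/- replicate 1 and Tlr7-/- replicates 2 and 3, gave the contrasts within the knockout group, with the spread pooled over all libraries. The split follows the style of the library names in the labels, in which replicate 1 is named like the WT libraries. Tlr7 was below the filter and was compared by an exact permutation test of CPM.

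Gene lists were tested with camera from limma 3.58.1 at a preset correlation of 0.01, again with an estimated correlation, and with fry, each adjusted over the 27 lists with at least 5 tested members. The list of red blood cell genes had 1 tested member and that of sex-linked genes had 4, so neither was tested. Members were also adjusted over the list alone. Choices made before the data were examined were the tests, the samples, the 29 lists and the rule for named genes. That rule took Tlr7, the 12 higher and 12 lower genes with the largest change among those past the threshold, or the 10 with the smallest p if fewer than 10 passed, up to 4 members per list with the smallest p, and the sex-linked genes per sample. Genes changed in both parts of the knockout group, and the genes named there, were added after the data were seen.

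Alternative tests were DESeq2 1.42.0 (Wald test), limma-voom and edgeR's exact test. Others were DESeq2's size factors, library size alone, other filters, limma on the authors' RPKM with pseudocounts of 0.1, 0.5 and 1, and a replicate block. The naming style was also used as a covariate. Knockout libraries of each naming style were compared alone with WT, and each library was left out in turn. After the data were seen, the trend of each library with GC content and length was removed by natural splines with 5 degrees of freedom as offsets, and libraries were thinned to equal depth. The overlap of contrasts that share controls was compared with 20 simulations without an effect. Figures were drawn with matplotlib 3.10.9. Of 128 named genes, 16 overlap another gene with counts, 13 of them on the opposite strand.

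The procedure was tested on simulated data. With 3 against 3 libraries and 13947 genes, edgeR recovered 84.7% of changes of 2-fold and 68.3% of 1.5-fold when the spread was that between libraries of the same naming style. With the spread between all libraries of a group it recovered 69.3% and 22%. Replicate 1 against WT recovered 74.3% of 2-fold and 48% of 1.5-fold changes, and replicates 2 and 3 against WT recovered 81.3% and 62%. Over 3 simulations, replicate 1 against WT gave 58 false calls beside 223 true calls of 2-fold and 144 of 1.5-fold changes. Replicates 2 and 3 against WT gave 54 false calls, beside 244 and 186. With 3 against 3 libraries, false calls numbered 42 with the same-style spread and 31 with the spread between all libraries. In each of these settings false calls were a larger share of all calls than the adjusted threshold allows. A list shifted by 0.5 on the log2 scale was called in 3 of 3 simulations with 0 other lists. Simulated genes varied independently, so this does not test false calls of lists whose members are correlated. In the main comparison the estimated correlation was 0.853 for immediate early genes. A simulated GC trend gave 3349 calls before and 0 after its removal. That trend was made from the same GC values that the correction uses, so its removal does not show that the correction is complete in the data.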

Results

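Messenger RNA was sequenced from cultured mouse neurons that lacked Tlr7, an endosomal receptor for single-stranded RNA, and from wild-type (WT) neurons. The cultures mixed cortical and hippocampal primary neurons of C57BL/6 background and were collected on day 18 in vitro. There were 3 WT and 3 Tlr7-/- libraries. Counts assigned to genes came to 25696625, 23351002 and 24627061 in WT replicates 1 to 3 and to 25557749, 23272450 and 24393123 in Tlr7-/- replicates 1 to 3. Of the 25814 genes listed, 7852 had no count in any library and 13947 were tested. Nothing in the labels says that the replicates came from separate cultures or animals, so the p-values measure only the spread between these samples. Y-linked counts, given at the end, differed between libraries of each genotype.

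The Tlr7-/- libraries did not form a single group. Replicate 1 carries the same style of library name as the WT libraries, per the labels, and replicates 2 and 3 carry another. On the first principal component, which held 62.8% of the variance, Tlr7-/- replicates 2 and 3 scored 46.3 and 44.6, while the other 4 libraries scored between -29 and -15.6. Mitochondrially encoded genes took 4.4% and 4.19% of counts in replicates 2 and 3, against 2.6% to 3.14% in the other 4. A rank correlation was taken across genes between a gene's deviation from its mean and its GC content. It was -0.545 and -0.46 in these replicates, and 0.306 (Tlr7-/- replicate 1) to 0.513 in the others. With transcript length it was -0.449 to -0.345 in WT, -0.0954 in Tlr7-/- replicate 1, and 0.372 and 0.429 in replicates 2 and 3. By length, replicate 1 thus lay between WT and replicates 2 and 3. Genes are not independent replicates in these measures. Because all 3 WT libraries carry the first naming style, values are given both for all 3 Tlr7-/- libraries and for replicate 1 and replicates 2 and 3 apart.

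**Figure D1:**
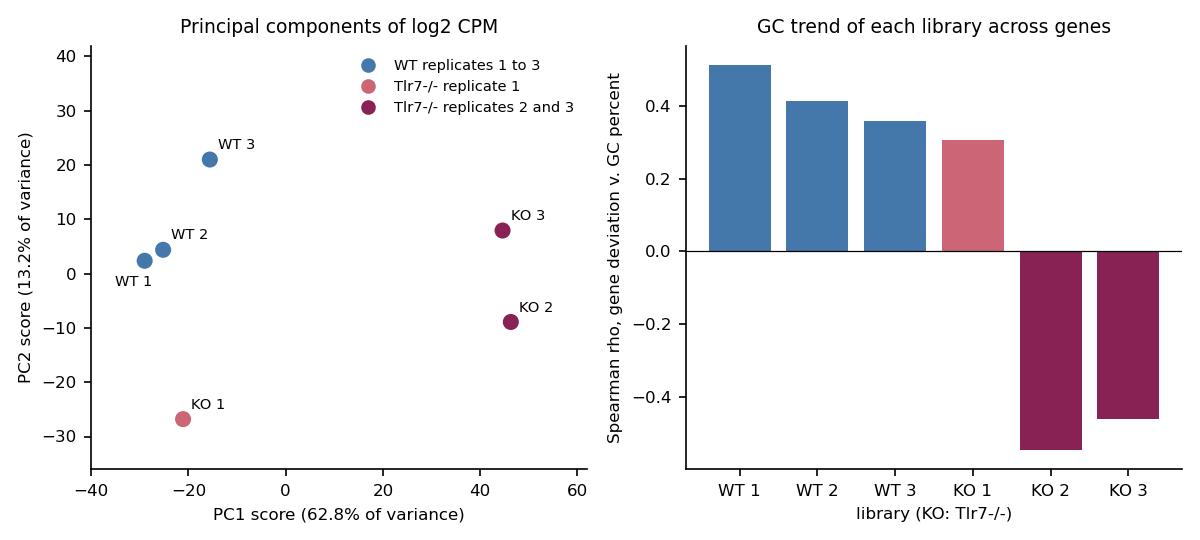
The 6 libraries on the first and second principal components of log2 CPM, with the share of variance on each axis, and bars of Spearman's rho across genes between a gene's deviation and its GC percent. Tlr7-/- replicates 2 and 3 lie at 46.3 and 44.6 on the first axis, apart from the other 4 libraries at -29 to -15.6, and have rho of -0.545 and -0.46.

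The first comparison asked whether the Tlr7 message differed between the genotypes. Tlr7 (ENSMUSG00000044583, GRCm38 chromosome X, 167304929 to 167330558, minus strand) was close to the limit of detection in both. Its counts in replicates 1 to 3 were 4, 8 and 4 in WT and 3, 5 and 5 in Tlr7-/- neurons. The mean level was 0.22 ± 0.106 CPM (counts scaled to library size; SD, n = 3) in WT and 0.179 ± 0.0536 CPM (SD, n = 3) in Tlr7-/- neurons (two-sided exact permutation p = 0.8, where 0.1 is the smallest p that 3 against 3 allows). The ratio of pooled counts was 0.818 with a 95% interval of 0.362 to 1.81, which covers counting error only. A difference in Tlr7 was therefore not detectable at this depth, and its level does not check the genotype labels.

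Tlr8, the neighbouring gene that encodes a related endosomal receptor (ENSMUSG00000040522, chromosome X, 167242696 to 167264329, minus strand), was scarcely counted in WT and counted in each Tlr7-/- library. Its counts were 0, 0 and 6 in WT replicates 1 to 3 and 61, 87 and 93 in Tlr7-/- replicates 1 to 3. The mean was 0.0812 ± 0.141 CPM in WT and 3.31 ± 0.803 CPM in Tlr7-/- neurons (SD, n = 3 each; two-sided exact permutation p = 0.1, the smallest possible). The ratio of pooled counts was 40.4, with a 95% interval of 18.3 to 111. The fitted log2 fold change was 5.25 ± 0.78 (SE), with an edgeR adjusted p of 0.112 over all genes tested. In the fit with 3 groups, whose spread is pooled over all libraries, Tlr8 had a log2 fold change of 4.80 ± 0.765 (SE) in replicate 1. In replicates 2 and 3 it had 5.43 ± 0.648 (SE; edgeR adjusted p = 0.000239).

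Other genes beside Tlr7 on chromosome X did not share this size of difference. Their log2 fold changes were 0.18 for Prps2 (edgeR adjusted p = 0.488), -0.40 for Tmsb4x (edgeR adjusted p = 0.138), 0.38 for Frmpd4 (edgeR adjusted p = 0.118) and -0.82 for Mid1 (edgeR adjusted p = 0.116). Of the 28 tested genes in the list of genes near Tlr7, 0 passed over all genes tested, and adjusted over the list alone 4 were higher and 1 was lower. Reps2 (0.56) and Ap1s2 (0.45) had the next smallest p in that list, with 0.17 and -0.03 after removal of each library's trend with GC content and length, where the list's median was -0.0061. As a group the list did not pass (camera adjusted p = 0.0569, median log2 fold change 0.17), with medians of -0.03 in replicate 1 and 0.26 in replicates 2 and 3. Without WT replicate 3 it was called higher (camera adjusted p = 0.0194).

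**Figure D2:**
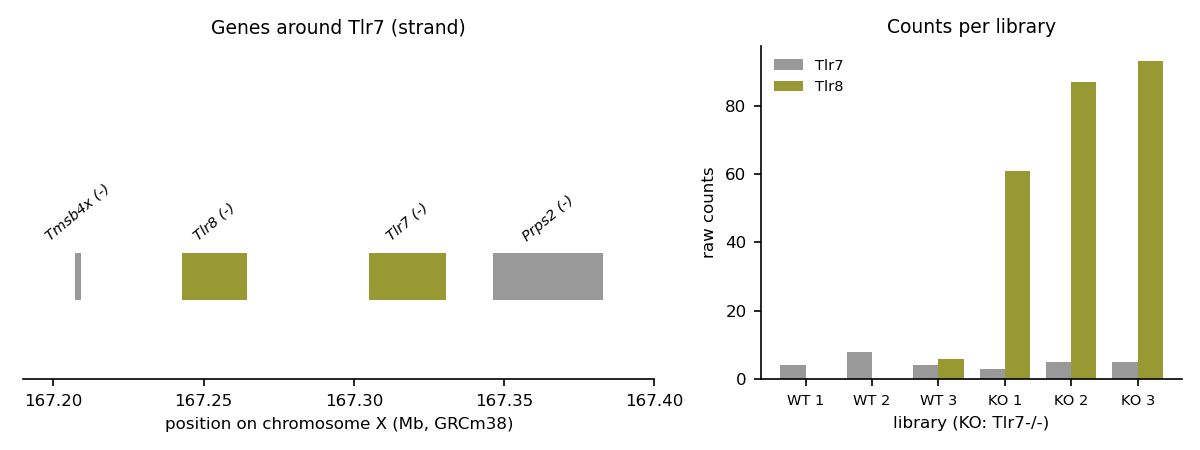
Map of the genes around Tlr7 on GRCm38 chromosome X (position in Mb, strand in brackets), and bars of the raw counts of Tlr7 and Tlr8 in each of the 6 libraries. Tlr8 has 61, 87 and 93 counts in the Tlr7-/- libraries and 0, 0 and 6 in the WT libraries, while Tlr7 has 3 to 8 in every library.

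The second comparison asked which genes differed between Tlr7-/- and WT neurons with all 6 libraries. The 10 genes with the smallest p are given here because fewer than 10 passed the threshold. Aldh1a3, an enzyme that makes retinoic acid (ENSMUSG00000015134, chromosome 7, 66390890 to 66427517, minus strand), had 1.85 ± 0.192 CPM in WT and 9.43 ± 1.71 CPM in Tlr7-/- neurons (SD, n = 3 each), a log2 fold change of 2.35 ± 0.19 (SE; edgeR adjusted p = 0.0739). Gpr17, a receptor of maturing oligodendrocyte precursors (ENSMUSG00000052229, chromosome 18, 31942997 to 31949636, minus strand), had 273 ± 40.5 CPM in WT and 124 ± 12.2 CPM in Tlr7-/- neurons (SD, n = 3 each). Its log2 fold change was -1.14 ± 0.13, and it lies within Lims2 on the opposite strand. Hmgb2, a chromatin protein abundant in dividing cells (ENSMUSG00000054717, chromosome 8, 57511907 to 57515999, plus strand), had 34.8 ± 0.251 CPM in WT and 15.3 ± 2.14 CPM in Tlr7-/- neurons (SD, n = 3 each), with a log2 fold change of -1.18 ± 0.12.

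Cacna1e, which encodes a voltage-gated calcium channel subunit, had a log2 fold change of 0.60 ± 0.07 (SE) on the higher side. Tenm2, which encodes a teneurin adhesion protein of synapses, had 0.51 ± 0.07, and Zkscan16, a zinc finger gene, had 0.94 ± 0.11. On the lower side were Higd1a, a hypoxia-inducible mitochondrial protein gene (log2 fold change -0.64 ± 0.08), Nkd1, an antagonist of Wnt signalling (-0.90 ± 0.11), Akr1b3, which encodes aldose reductase (-0.57 ± 0.08), and Cnn2, which encodes an actin-binding calponin (-1.30 ± 0.18). The edgeR adjusted p of the 9 genes other than Aldh1a3 was 0.112. For each of the 10, all 3 Tlr7-/- libraries lay beyond all 3 WT libraries. Cacna1e had 0.22 and Tenm2 0.32 after removal of the trend with GC content and length, and the other 8 stayed within 1.5 times.

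With edgeR's quasi-likelihood test and Benjamini-Hochberg adjustment, 0 of 13947 genes passed an adjusted p of 0.05, and 3932 had an unadjusted p under 0.05 (2171 higher and 1761 lower in Tlr7-/- neurons). DESeq2's Wald test called 1716 genes (1067 higher, 649 lower), edgeR's exact test called 1028 (651 higher, 377 lower) and limma-voom called 0. The 3 Tlr7-/- libraries lay beyond all 3 WT libraries for 4565 genes (2306 higher, 2259 lower), which is 32.7% of those tested. Chance would give 10% if the 6 libraries were exchangeable. Tlr7-/- replicates 2 and 3 stood apart from the other libraries, so 10% is too low a reference and the excess does not measure a genotype effect. Omitting Tlr7-/- replicate 1 raised the edgeR count from 0 to 6922 genes. Of the 127 tested genes named by the rule or, for the fourth comparison, after the data were seen, 59 moved by over 1.5 times or changed sign (10 genes) after each library's trend with GC content and length was removed; corrected values stand beside such genes.

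**Figure D3:**
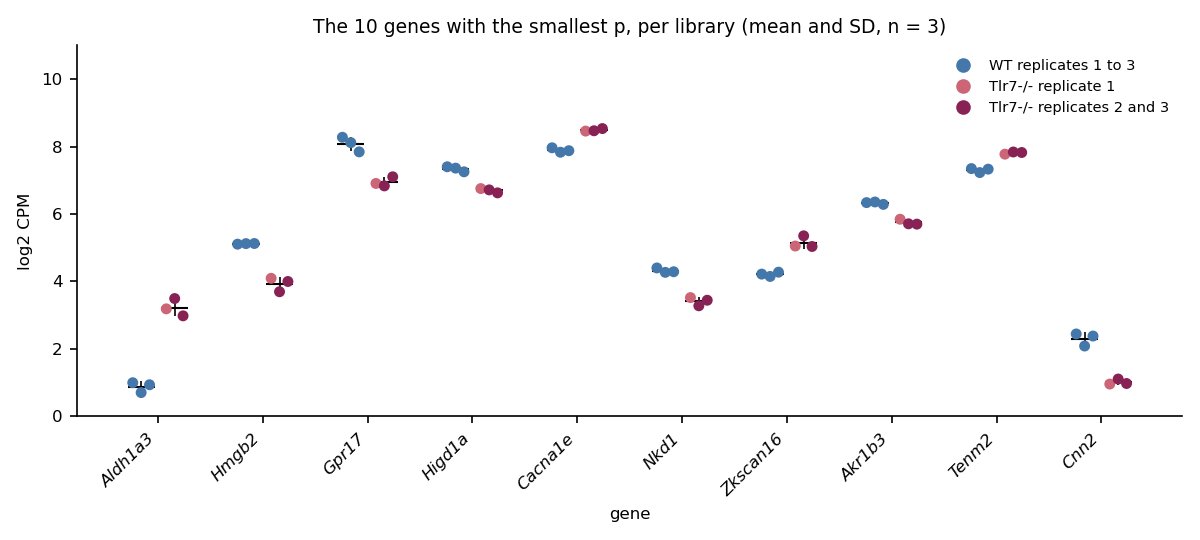
Log2 CPM of the 10 genes with the smallest p, with a point per library and the mean and SD of each group (n = 3). For each of the 10 genes all 3 Tlr7-/- libraries lie on the same side of all 3 WT libraries.

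The third comparison asked whether groups of genes moved together, using 29 lists fixed before the data were examined, of which 27 had enough tested members. Limma's camera with its preset correlation called 9 lists, 2 higher and 7 lower in Tlr7-/- neurons. With an estimated correlation 0 of the 27 lists passed, and fry's directional test also called 0. Fry's test of change in either direction, which does not ask whether members moved together, gave adjusted p from 0.0196 (astrocytes) to 0.611 (microglia). In the main comparison no member of any list passed over all 13947 genes.

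Genes of the oligodendrocyte lineage fell as a group in Tlr7-/- neurons. These genes mark the cells that form myelin and their precursors. The median log2 fold change of the 22 tested members was -0.87 (camera adjusted p = 1.31e-13; adjusted p = 0.376 with an estimated correlation). Adjusted over the list alone 14 members were lower and 0 higher, against 0 over all genes tested, and 16 had all 3 Tlr7-/- libraries below all 3 WT libraries. Examples besides Gpr17 were Cnp, a myelin enzyme (log2 fold change -0.81 ± 0.14), Sox10, a transcription factor of the lineage (-1.02 ± 0.18), and Mag, a myelin glycoprotein (-1.02 ± 0.20). Sox10 had -0.55 after removal of the trend with GC content and length. The size of the fall differed between members, and 1 of the 22 was higher. Pdgfra, a receptor of precursors, had -0.17 ± 0.10, and Cspg4, a proteoglycan of precursors, had -0.07 ± 0.11. The median was -0.45 in replicate 1 and -1.10 in replicates 2 and 3.

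**Figure D4:**
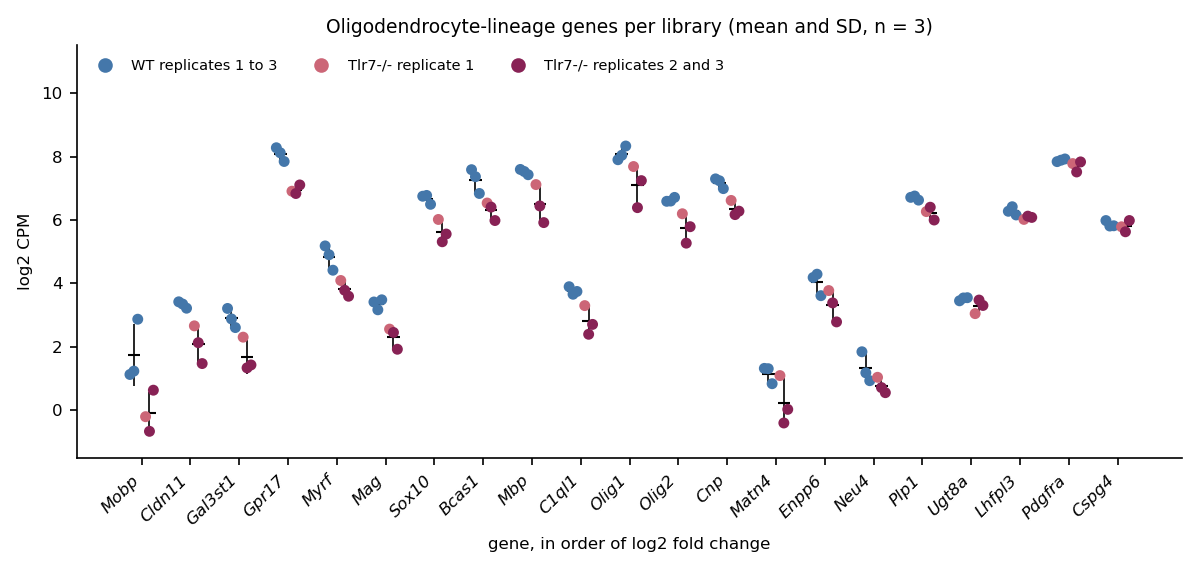
Log2 CPM of 21 oligodendrocyte lineage genes with a point per library and the mean and SD of each group (n = 3); Ermn, whose WT mean is under 1 CPM, is left out. Over all 22 tested members the median log2 fold change is -0.87, with -0.45 in Tlr7-/- replicate 1 and -1.10 in replicates 2 and 3.

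The other glial and vascular lists did not pass with all 6 libraries. Among 31 astrocyte genes the median log2 fold change was -0.15 (camera adjusted p = 0.108), and adjusted over the list alone 2 were higher and 4 lower. Slc4a4, a bicarbonate transporter, had 0.44 ± 0.08, while Vim, an intermediate filament gene, had -0.61 ± 0.12, and Ntsr2 had -0.66 ± 0.16. In replicate 1 alone the astrocyte list was called lower (median -0.21, camera adjusted p = 0.0015; adjusted p = 0.546 with an estimated correlation). Corrected for the trend with GC content and length, Slc4a4 had 0.16 and the list's median was -0.07, with -0.15 in replicate 1 (camera adjusted p = 0.00126; adjusted p = 0.632 with an estimated correlation). The astrocyte list was called lower without WT replicate 2, Tlr7-/- replicate 2 or Tlr7-/- replicate 3 (camera adjusted p = 0.0369, 0.0221 and 0.0398). The 14 microglial genes had a median of 0.29 (camera adjusted p = 0.294), with -1.22 in replicate 1 and 0.49 in replicates 2 and 3; without WT replicate 3 this list was called higher (camera adjusted p = 5.33e-06). C1qa, a complement component of microglia, had a log2 fold change of 2.44 ± 1.15, and -0.98 with the naming style as a covariate. The camera adjusted p was 0.403 for 8 endothelial genes, 0.294 for 20 genes of pericytes, fibroblasts and meninges, and 0.879 for 13 genes of choroid plexus and ependyma. Adjusted over the list alone, 0 members of these 4 lists passed. Examples were Slc2a1, a glucose transporter (log2 fold change -0.73), Thbs1 (-0.69), Col6a3 (0.63) and Cdkn1c (-2.09).

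Voltage-gated ion channel genes rose as a group in Tlr7-/- neurons. The median log2 fold change of the 47 tested members was 0.23 (camera adjusted p = 0.000304; adjusted p = 0.535 with an estimated correlation). Adjusted over the list alone 12 were higher and 1 lower, against 0 over all genes tested. Examples were Cacna1e, Cacna2d3, an accessory calcium channel subunit (0.34 ± 0.06), and Kcnb2, a delayed rectifier potassium channel (0.75 ± 0.16), while Kcnmb4, an accessory subunit of calcium-activated potassium channels, had -0.66 ± 0.14. The median was 0.07 in replicate 1, where the list did not pass (camera adjusted p = 0.42), and 0.30 in replicates 2 and 3. The median after correction for GC content and length was 0.13 (camera adjusted p = 0.0149; adjusted p = 0.646 with an estimated correlation), with -0.0097 in replicate 1 (camera adjusted p = 0.225), and Kcnb2 had 0.08.

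Synapse, axon and cell-identity lists did not pass with all 6 libraries. The camera adjusted p was 0.0772 for 47 excitatory synapse genes, 0.705 for 41 presynaptic genes, 0.274 for 40 GABAergic genes, 0.0531 for 54 axon guidance genes, 0.428 for 34 genes of excitatory neuron subtypes and 0.467 for 17 striatal genes. Adjusted over the list alone, 10 excitatory synapse genes were higher and 1 lower, among them the NMDA receptor subunits Grin2a (log2 fold change 0.61 ± 0.09) and Grin2b (0.89 ± 0.18) and the kainate receptor subunit Grik2 (0.56 ± 0.10). On the same basis 5 presynaptic genes were higher and 2 lower, such as Pclo, an active zone scaffold (0.57 ± 0.14), and Stx1a, a vesicle fusion protein (-0.36 ± 0.09). For GABAergic genes the counts adjusted over the list alone were 3 higher and 0 lower, with the receptor subunit Gabrb1 (0.67 ± 0.12), which overlaps a neighbouring gene with counts, as an example. For axon guidance they were 7 higher and 2 lower, with the ephrin receptors Epha3 (0.84 ± 0.16), Epha5 (0.51 ± 0.07) and Epha8 (-0.68 ± 0.11). For neuron subtypes they were 2 higher and 1 lower, with Zbtb20 at 0.85 ± 0.13 and Rprm at -0.81 ± 0.13, and for striatal genes 0 higher and 1 lower, with Syndig1l at -0.63 ± 0.14. The axon guidance list was called higher without WT replicate 3 or Tlr7-/- replicate 2 (camera adjusted p = 0.0419 and 0.00698), and the excitatory synapse list without Tlr7-/- replicate 2 (camera adjusted p = 0.00816). In replicate 1 against WT the excitatory synapse, axon guidance and GABAergic lists were called higher (camera adjusted p = 0.00112, 0.00112 and 0.00739; adjusted p = 0.546 with an estimated correlation for each). These replicate 1 values after correction for GC content and length were 0.118, 0.0798 and 0.0248 (adjusted p = 0.632 with an estimated correlation for each), so of these only the GABAergic list passed. With all 6 libraries the corrected medians were 0.02 for excitatory synapse and 0.0079 for axon guidance genes (camera adjusted p = 0.787 for each), and the camera tests of presynaptic and GABAergic genes turned to the lower direction (0.404 and 0.885). Corrected log2 fold changes were 0.16 for Grin2a, 0.32 for Grin2b, -0.04 for Grik2, 0.06 for Pclo, -0.06 for Stx1a and 0.12 for Gabrb1. They were 0.09 for Epha5, -0.31 for Epha8, 0.23 for Zbtb20, -0.51 for Rprm and -0.29 for Syndig1l.

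Neuropeptide and immediate early genes fell as groups, and each did so through Tlr7-/- replicates 2 and 3. The 36 immediate early genes, which neuronal activity induces, had a median log2 fold change of -0.83 (camera adjusted p = 9.11e-06; adjusted p = 0.553 with an estimated correlation). Their median was 0.13 in replicate 1 and -1.77 in replicates 2 and 3, and replicate 1 taken alone gave a call in the higher direction (camera adjusted p = 0.00112; adjusted p = 0.685 with an estimated correlation). Examples were Nr4a2 (-1.06 ± 0.32) and Atf3 (-1.73 ± 0.68), and adjusted over the list alone 0 passed. The 27 neuropeptide and granin genes had a median of -0.34 (camera adjusted p = 0.00588; adjusted p = 0.546 with an estimated correlation), with 0.02 in replicate 1 and -0.78 in replicates 2 and 3. Examples were Cort, which encodes cortistatin (-1.23 ± 0.31), and Trh, which encodes thyrotropin-releasing hormone (-1.85 ± 0.48), and adjusted over the list alone 0 passed. The neuropeptide list did not pass without Tlr7-/- replicate 3 (camera adjusted p = 0.0609) or after removal of the trend with GC content and length (median -0.09, camera adjusted p = 0.0765), where Cort had -0.76.

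The innate immune lists, which hold the pathway that Tlr7 acts in, did not pass. The 26 tested genes of the Toll-like receptor pathway had a median log2 fold change of 0.07 (camera adjusted p = 0.12). Adjusted over the list alone 2 were higher, Tlr8 and Tlr3, a receptor for double-stranded RNA (0.93 ± 0.19), and 0 were lower. Tab2, a signalling adaptor, had 0.28 ± 0.07 and Slc15a4, an endolysosomal transporter, had -0.31 ± 0.10. Among 22 cytokine and NF-kB target genes the median was -0.10 (camera adjusted p = 0.32), and adjusted over the list alone 1 was lower, Vcam1, an adhesion molecule (-0.55 ± 0.10). The 32 interferon-stimulated genes had a median of 0.09, a mean of -0.02 and a camera test in the lower direction (adjusted p = 0.946), so these differed in sign; adjusted over the list alone 0 passed. Examples were Psmb9, an immunoproteasome subunit that overlaps Tap1 (-1.42 ± 0.47), and Ifit2 (0.63 ± 0.23). After removal of each library's trend with GC content and length, the Toll-like receptor list was called higher (camera adjusted p = 0.0305; adjusted p = 0.574 with an estimated correlation) and the interferon test turned to the higher direction (0.819). Tlr3 then had 0.61, Slc15a4 -0.16 and Vcam1 -0.82.

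Lists of energy metabolism, translation, division and secretory stress fell as groups, while mitochondrially encoded genes rose. The 23 hypoxia and glycolysis genes had a median log2 fold change of -0.32 (camera adjusted p = 2.09e-08; adjusted p = 0.535 with an estimated correlation), with -0.26 in replicate 1 and -0.44 in replicates 2 and 3. Adjusted over the list alone 11 were lower and 0 higher, including the glycolytic enzymes Pfkl (-0.51 ± 0.08), Tpi1 (-0.47 ± 0.09) and Eno1 (-0.32 ± 0.07), of which Tpi1 had -0.23 and Eno1 -0.03 after removal of the trend with GC content and length. The 28 proliferation and progenitor genes had a median of -0.55 (camera adjusted p = 1.35e-05; adjusted p = 0.546 with an estimated correlation), with -0.97 in replicate 1 and -0.39 in replicates 2 and 3. Examples were the replication genes Mcm2 (-0.65 ± 0.16) and Pcna (-0.26 ± 0.07) and the mitotic cyclin Ccnb1 (-0.90 ± 0.28), and adjusted over the list alone 0 passed. Without Tlr7-/- replicate 1 the proliferation list did not pass (camera adjusted p = 0.0803).

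The 47 cytosolic ribosomal protein genes had a median of -0.37 (camera adjusted p = 1.98e-12; adjusted p = 0.546 with an estimated correlation), with -0.06 in replicate 1 (camera adjusted p = 0.0126; adjusted p = 0.765 with an estimated correlation) and -0.55 in replicates 2 and 3. After removal of the trend with GC content and length the median was -0.10 (camera adjusted p = 0.00308; adjusted p = 0.819 with an estimated correlation), and in replicate 1 it turned to 0.05 (camera adjusted p = 0.231). Examples were Rpl27 (-0.97 ± 0.24) and Rpl8 (-0.51 ± 0.16), and adjusted over the list alone 0 passed although 31 had an unadjusted p under 0.05. The 13 mitochondrially encoded genes rose with a median of 0.41 (camera adjusted p = 0.00026; adjusted p = 0.546 with an estimated correlation), with 0.09 in replicate 1, where the list did not pass (camera adjusted p = 0.815), and 0.59 in replicates 2 and 3. Examples were mt-Nd5 (0.58 ± 0.17) and mt-Nd4l (0.93 ± 0.28), subunits of respiratory complex I, and adjusted over the list alone 0 passed. The 28 genes of the unfolded protein and amino acid stress response had a median of -0.21 (camera adjusted p = 0.00607; adjusted p = 0.581 with an estimated correlation), with 0.08 in replicate 1 and -0.40 in replicates 2 and 3. Examples were the endoplasmic reticulum genes Creld2 (-0.63 ± 0.13) and Sdf2l1 (-1.15 ± 0.27), adjusted over the list alone 0 passed, and without Tlr7-/- replicate 3 the list did not pass (camera adjusted p = 0.12). Its median after this correction was -0.07 (camera adjusted p = 0.0456; adjusted p = 0.825 with an estimated correlation). Corrected values were -0.59 for Rpl27, -0.08 for Rpl8, 0.28 for mt-Nd5 and -0.36 for Creld2.

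Heat shock, cholesterol synthesis and substrain lists did not pass, and adjusted over the list alone 0 of their members passed. The 14 heat shock genes had a median of -0.18 (camera adjusted p = 0.12), with Hspe1, a mitochondrial chaperonin, at -0.24 ± 0.07. The 24 cholesterol synthesis genes had a median of 0.01 and a mean of 0.03 with a camera test in the lower direction (adjusted p = 0.927), with Mvd, an enzyme of the mevalonate pathway, at -0.32 ± 0.08. The 9 genes known to differ between mouse substrains had a median of 0.07 (camera adjusted p = 0.412), with Trim12a at 1.31 ± 0.36 and Gabra2 at 0.47 ± 0.17. Such genes may differ in either direction, which a directional test can miss. Fry's test of change in either direction gave adjusted p = 0.0231 for them, 0.0822 for heat shock and 0.294 for cholesterol synthesis genes. After removal of the trend with GC content and length, the heat shock list and that of excitatory neuron subtypes were called lower (camera adjusted p = 0.0456 and 0.0303; adjusted p = 0.646 with an estimated correlation for each), and the cholesterol test turned to the higher direction (0.819). Hspe1 then had -0.08, Mvd 0.08 and Gabra2 0.08.

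**Figure D5:**
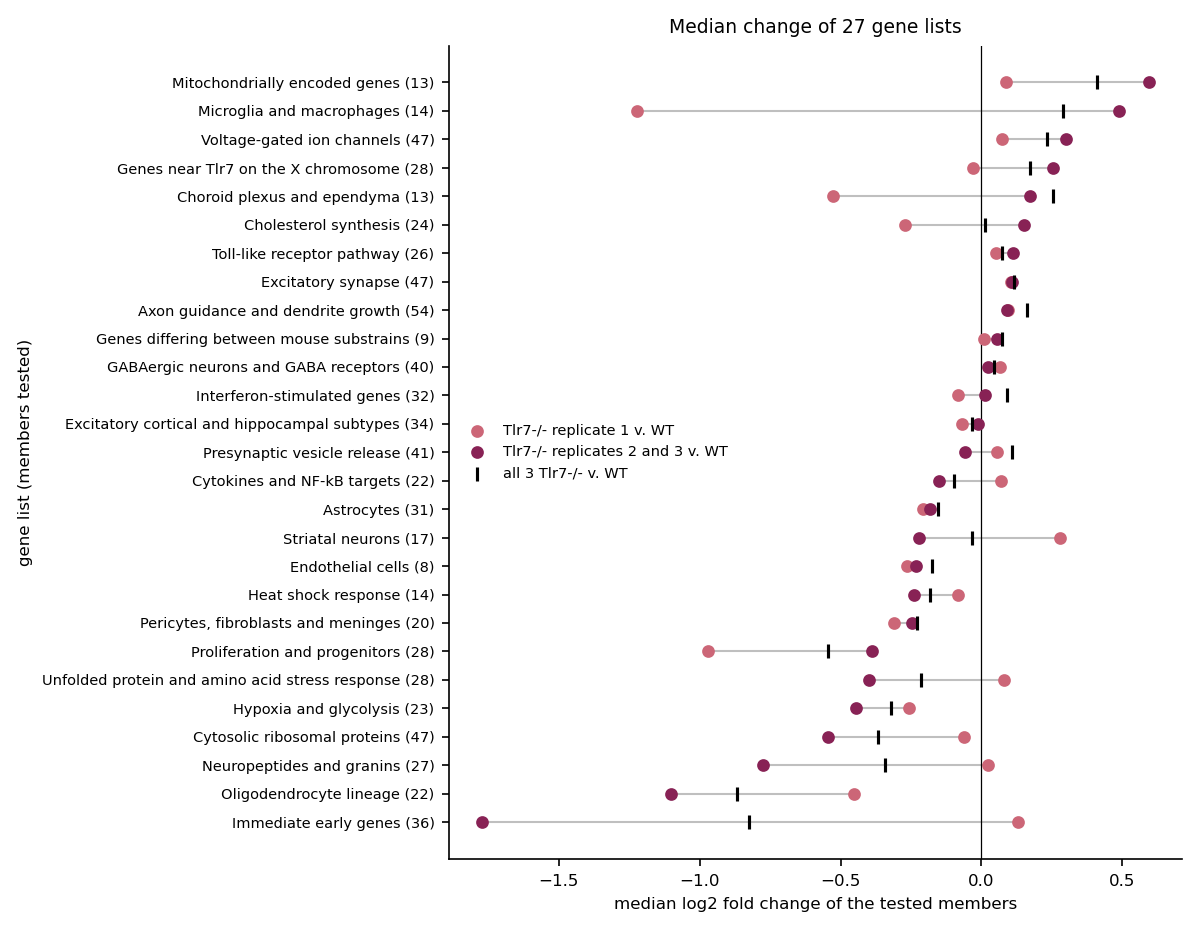
Median log2 fold change of the tested members of each of the 27 gene lists for all 3 Tlr7-/- libraries (bars) and for replicate 1 and replicates 2 and 3 apart (points), each against the 3 WT libraries. Immediate early genes have medians of 0.13 in replicate 1 and -1.77 in replicates 2 and 3, while oligodendrocyte lineage genes have -0.45 and -1.10.

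The fourth comparison, chosen after the data were seen, asked which genes changed in the same direction in Tlr7-/- replicate 1 and in replicates 2 and 3. Aldh1a3, Tlr8, Grin2a and Grin2b rose in both, and Hmgb2, Lmnb1 and Grm3 fell in both. The 12 higher and 12 lower genes named here had the smallest p over both contrasts and were also chosen after their values were seen. Higher genes had log2 fold changes, in replicate 1 and in replicates 2 and 3, of 2.30 and 2.37 for Aldh1a3, 4.80 and 5.43 for Tlr8, 0.45 and 0.69 for Grin2a, and 0.40 and 1.08 for Grin2b. The same pair of values was 0.57 and 0.61 for Cacna1e, 0.53 and 0.50 for Epha5, 0.47 and 0.53 for Tenm2, and 0.84 and 0.99 for Zkscan16. For the cadherin family it was 0.46 and 0.40 for Pcdh17, 0.71 and 0.56 for Cdh20, and 0.48 and 0.87 for Fat3. For St8sia2, which adds polysialic acid to neural adhesion molecules, it was 0.87 and 0.50.

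Lower genes in both included Hmgb2, with log2 fold changes of -1.03 in replicate 1 and -1.26 in replicates 2 and 3. The same pair of values was -0.75 and -0.60 for Lmnb1, which encodes a nuclear lamin, -0.48 and -0.36 for Stmn1, a microtubule regulator, and -0.54 and -0.36 for Fabp5, a fatty acid carrier. It was -0.58 and -0.67 for Higd1a, -0.48 and -0.62 for Akr1b3, -0.80 and -0.96 for Nkd1, and -1.05 and -0.51 for Grm3, a metabotropic glutamate receptor. It was -0.67 and -1.20 for Fxyd7, a regulator of the sodium pump. Fxyd7 had -0.51 and -0.46 after removal of the trend with GC content and length. The uncorrected pair was -0.67 and -1.23 for Ppp1r14b, -0.71 and -0.62 for Afap1l2, and -0.56 and -0.33 for Gng12. The edgeR adjusted p of these 24 genes in replicate 1 ranged from 0.0112 to 0.0317. After removal of the trend with GC content and length 16 of the 24 were called in both. The other 8 had, in replicate 1 and in replicates 2 and 3, 0.41 and 0.12 (Cacna1e), 0.29 and 0.10 (Grin2a), 0.20 and 0.38 (Grin2b), 0.41 and -0.11 (Epha5), 0.33 and -0.10 (Pcdh17), 0.31 and 0.27 (Fat3), -0.36 and 0.0021 (Stmn1), and -0.56 and 0.30 (Ppp1r14b).

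Replicate 1 differed from WT at 200 genes (124 higher, 76 lower), and replicates 2 and 3 differed from WT at 6915 (3407 higher, 3508 lower), each by edgeR's quasi-likelihood test. Both gave the same direction for 105 genes (67 higher, 38 lower) and opposite directions for 43. Independent lists of these sizes would share 30.3 higher and 19.1 lower genes. Both contrasts use the same WT libraries, and 20 simulations with no effect gave a mean overlap of 0.65 genes and at most 3. In the simulations neither contrast held changed genes, whereas replicates 2 and 3 differed from WT at 6915. The simulated overlap is therefore no reference for the overlap observed. The covariance of the fold changes was 0.0398, against 0.0233 in the simulations. It was 0.0185 after removal of the trend with GC content and length, for which no simulated value is given. Their correlation across genes was 0.152, against 0.304 in the simulations. As the simulations lack the changes of replicates 2 and 3, neither measure decides whether the contrasts share more than the WT libraries. Leaving out 1 library gave 9 genes without WT replicate 1, 4 without WT replicate 2, 211 without WT replicate 3, 170 without Tlr7-/- replicate 2 and 177 without Tlr7-/- replicate 3. After removal of each library's trend with GC content and length the count was 59, of which 41 were among the 105.

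The fifth comparison asked whether the naming of the libraries went with expression among the Tlr7-/- samples. Immediate early, ribosomal protein, neuropeptide and stress response genes were lower in replicates 2 and 3 than in replicate 1, and ion channel, mitochondrially encoded and cholesterol synthesis genes were higher. Of these, immediate early genes had a median log2 difference of -1.86 (camera adjusted p = 1.24e-33; adjusted p = 0.652 with an estimated correlation) and 32 members lower. Ribosomal protein genes had -0.48 (camera adjusted p = 1.04e-21; adjusted p = 0.652 with an estimated correlation) and 44 members lower. The camera adjusted p was 3.64e-05 for neuropeptides (median -0.84), 1.54e-06 for the stress response (-0.34), 1.69e-05 for ion channels (0.34), 4.43e-05 for mitochondrially encoded genes (0.59) and 7.96e-06 for cholesterol synthesis (0.42). For each of these the adjusted p = 0.652 with an estimated correlation. With correction for GC content and length each of the 7 lists was called in the same direction (adjusted p = 0.513 with an estimated correlation for each), with medians of -0.29 for ribosomal protein genes, -0.48 for neuropeptides and 0.25 for mitochondrially encoded genes. Among single genes, chosen after their values were seen, Scand1 had a log2 difference of -5.98, Pcsk1n of -4.39, Jund of -3.11 and Arc, an activity-induced synaptic gene, of -3.16. On the higher side were Pnisr at 1.61, Kcnc2, a potassium channel gene, at 1.56, Ogt at 1.38 and Mef2c, a neuronal transcription factor, at 0.98. Corrected for that trend, Jund had -1.54 and Mef2c 0.57. Lars2, a mitochondrial leucyl-tRNA synthetase, had 21512 and 21450 counts in replicates 2 and 3 and 1292 to 2556 in the other 4 libraries.

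Between replicates 2 and 3 and replicate 1, 4404 genes differed by edgeR's quasi-likelihood test (2092 higher, 2312 lower), 31.6% of those tested. Replicate 1 stands alone on its side, so its spread is assumed to match that of the other groups. After removal of the trend with GC content and length 2607 genes differed, and 1923 were called both before and after.

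The last comparison set these values beside the authors' deposited edgeR table, in which 465 of 27420 genes have a false discovery rate under 0.05 (287 higher, 178 lower in Tlr7-/- neurons). Tlr8 has a log2 fold change of 5.26 in that table (false discovery rate 1.1e-20), Aldh1a3 2.39 (2.91e-15), Gpr17 -1.18 (1.18e-08), Hmgb2 -1.27 (7.41e-06) and Sox10 -1.07 (0.00022), while Tlr7 has 0.03 (false discovery rate 1). Of the 465 genes, 373 were tested here. All 373 had the same direction in the edgeR fit to the 6 libraries, 371 had an unadjusted p under 0.05, and 0 passed the adjusted threshold. Both comparisons draw on the same series, so the shared direction and the small p are no independent check. For 351 of them (94.1%) all 3 Tlr7-/- libraries lay beyond all 3 WT libraries, and 43 were among the 105 genes changed in both parts of the knockout group.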

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

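The contrast between the naming styles was planned, while the tests of GC content and length, depth, glial and microglial markers, flanking genes and splits of the libraries were chosen only after the result was seen. For genes called in opposite directions no number expected by chance was computed, so an excess of them is not shown.

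The knockout libraries with the second naming style differed from the knockout library with the first at 4404 genes, by edgeR's test of the difference itself. Against WT, 43 genes were called in opposite directions in replicate 1 and in replicates 2 and 3. Scored between these libraries, immediate early genes differed (camera adjusted p = 1.24e-33; adjusted p = 0.652 with an estimated correlation), with medians against WT of 0.13 and -1.77. Striatal neuron genes differed (camera adjusted p = 3.7e-05; adjusted p = 0.652 with an estimated correlation), with medians of 0.28 and -0.22. Cholesterol synthesis genes differed (camera adjusted p = 7.96e-06; adjusted p = 0.652 with an estimated correlation), with medians of -0.27 and 0.15.

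The first pattern weighed was the difference within the knockout group. A trend with GC content and length, as far as the splines capture it, is argued against as the whole cause. After each library's trend was removed 2607 genes differed, 1923 of them called before as well. Thinning the libraries to equal depth left 4374 genes, but totals differed by at most 1.10 times, so thinning changed too little to test depth. A difference between library or culture batches may underlie it and cannot be told apart from a biological difference between these samples, because 0 WT libraries carry the second naming style.

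The second pattern weighed was the lower level of oligodendrocyte lineage genes. The GC and length trend, as far as the splines capture it, is argued against as its whole cause. The median log2 fold change after correction was -0.70 (quartiles -0.90 and -0.49), against -0.87 before (quartiles -1.02 and -0.50). A lower glial content of every kind is also argued against, because astrocyte genes had a median of -0.15 (quartiles -0.35 and 0.08), but it stays open for replicate 1, where the quartiles of oligodendrocyte (-0.67 and -0.30) and astrocyte genes (-0.43 and 0.03, median -0.21) overlapped. A part played by the library series cannot be told apart, as only 1 knockout library shares the naming style of WT: in it 18 of 22 members lay below all 3 WT libraries, against 25% by chance, as did 20 of 31 astrocyte genes. Fewer cells of the lineage in the cultures, or lower expression in them, remain possible and untested. The small changes of Pdgfra and Cspg4 leave a fall of the precursors not shown.

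The third pattern weighed was Tlr8. Microglial RNA is argued against, since the median ratio of 22 microglial genes was 1.24 (quartiles 0.869 and 2.19; the highest, Cx3cr1, 14.8), under the lower bound of 18.3 for Tlr8, and Lyz2 had 920 counts in WT replicate 3 and 73 in Tlr7-/- replicate 1. A change of the whole flanking region is argued against by the 27 other tested genes near Tlr7, with a median log2 fold change of 0.17 (quartiles -0.10 and 0.38). Transcription that runs from an altered Tlr7 allele across the 40599 bases to Tlr8 may contribute and cannot be told apart from regulation of Tlr8, since gene counts do not cover that stretch and the labels do not describe the allele.

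The 10 splits of the 6 libraries are too few for a share under 0.05. The real split gave 0 genes and 9 lists, and the highest of the other splits gave 1 gene and 12 lists. As the real count of genes was 0, that count decides nothing. An unadjusted p under 0.05 was found for 3932 genes in the real split and for 2921 in the highest of the others, which set Tlr7-/- replicate 1 with WT replicates 1 and 2 against the rest and so kept the second naming style on 1 side.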

How the results depend on the processing

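The GC and length correction, the edgeR exact test, all alternatives of the genes changed in both knockout series, the agreement with the authors' table and some of those of the library series and the lists were chosen after seeing the data. The number of genes changed in Tlr7-/- neurons was 0 and became 1716 with the DESeq2 Wald test, 1028 with the edgeR exact test, 1 with no filter on low counts, 1 with the GC and length correction, 200 with library naming as a covariate, 320 with the first naming style only and 6922 with the second naming style only; leaving out 1 library gave 0 to 6922, where only the omission of Tlr7-/- replicate 1 gave a value above 0. DESeq2 size factors, library size, limma-voom, a mean CPM of at least 1, the authors' RPKM with each of 3 pseudocounts and an absolute log2 fold change of at least 1 gave 0. No WT library carries the second naming style. The setting with that style only compared Tlr7-/- replicates 2 and 3 with the 3 WT libraries, as did leaving out Tlr7-/- replicate 1. Its count therefore cannot separate genotype from naming style. Library naming as a covariate repeated the contrast of Tlr7-/- replicate 1 with WT. The number of called lists was 9 and became 0 with an estimated correlation and 0 with fry's directional test, and leaving out 1 library gave 8 to 12. Of 378 list values, 26 turned direction. With library naming as a covariate and with the first naming style only these were immediate early genes (adjusted p = 0.00112 and 0.000629), neuropeptides and granins (0.616 and 0.457), striatal neurons (3.39e-05 and 0.000177), the unfolded protein and amino acid stress response (0.42 and 0.438), cytokines and NF-kB targets (0.815 and 0.665), microglia (0.461 and 0.655) and choroid plexus (0.413 and 0.45), and with the first naming style only excitatory subtypes (0.981). With the GC and length correction these were interferon-stimulated genes (0.819), presynaptic genes (0.404), GABAergic genes (0.885) and cholesterol synthesis (0.819). Leaving out 1 library turned cytokines (without Tlr7-/- replicate 3, 0.993; range 0.131 to 0.993), interferon-stimulated genes (without WT replicate 1, 0.851, or Tlr7-/- replicate 1, 0.743; range 0.635 to 0.983), choroid plexus (without WT replicate 1, 0.998, or Tlr7-/- replicate 2, 0.859; range 0.562 to 0.998) and cholesterol synthesis (without WT replicate 3, 0.983, or Tlr7-/- replicate 1, 0.162; range 0.12 to 0.983). Genes changed in both knockout series (replicate 1, and replicates 2 and 3) numbered 105, against 175 with no filter, 59 with the GC and length correction and 4 to 211 with 1 library left out. Genes that differ between the library series numbered 4404, against 2607 with the GC and length correction and 3248 to 4828 with 1 library left out. Without Tlr7-/- replicate 1 neither of these results can be computed. The share of the authors' called genes with the same direction was 100%, against 97.9% with library naming as a covariate and 98.1% with the GC and length correction. The log2 ratio of Tlr7 was -0.32, with 1 library left out -0.51 to 0.15. Beyond the use of fewer samples or genes, the cause was not tested. Of 2632 values for 127 named genes, 469 passed the threshold in the same direction under an alternative and 20, of 15 genes, turned direction. With the GC and length correction these log2 values were 0.0043 for Ifi27, -0.042 for Grik2, -0.20 for Nlgn1, -0.033 for Snap25, -0.11 for Chordc1, 0.084 for Mvd, 0.023 for Pmvk, 0.21 for Rpl38, -0.031 for Ap1s2 and 0.055 for Ppp1r14b. With library naming as a covariate and with the first naming style only they were -0.976 and -0.979 for C1qa, -0.909 and -0.911 for Laptm5, -4.312 and -4.315 for C1qc, -0.077 and -0.082 for Enpp2, and -0.669 and -0.673 for Otx2.

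With a replicate block edgeR called 0 genes and camera called 9 lists. The correlation of deviations between libraries of the same number was 0.241, -0.0839 and 0.264. Between libraries of different number it was -0.278 to 0.124. Numbers 1 and 3 thus had the highest values and number 2 did not, so these values do not decide whether the numbers pair the samples. Depth limits Tlr7 and Tlr8: a count of 0 allows up to 0.129 CPM, and Tlr7 was near that level in every library.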

Other observations

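The test of gene length was chosen only after the result was seen, and the genes of the 2 opposite groups were named after their values were seen. How many genes independent lists would place in these opposite groups was not computed.

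The 43 genes called in opposite directions included Penk, Grp and Kcnc2. In replicate 1 expression was higher and in replicates 2 and 3 lower than WT for 27 genes, such as Penk, which encodes enkephalins (log2 fold changes 0.87 and -1.12), Grp, which encodes gastrin-releasing peptide (0.91 and -1.30), Cbln4, which encodes a cerebellin (1.12 and -1.02), and Nnat (0.71 and -1.71). The reverse held for 16 genes, such as Kcnc2, a potassium channel (-1.19 and 0.38), Syt2, a synaptotagmin (-2.60 and 0.72), and Col5a1, a collagen (-1.09 and 0.67). After removal of the trend with GC content and length 32 of the 43 were called in opposite directions, while Kcnc2 had -1.22 and 0.16 and passed in replicate 1 only. In replicate 1 alone, striatal neuron genes were called higher than WT as a list (median 0.28, camera adjusted p = 3.39e-05; adjusted p = 0.546 with an estimated correlation) and cholesterol synthesis genes lower (median -0.27, camera adjusted p = 2.87e-09; adjusted p = 0.546 with an estimated correlation).

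Microglial and Y-linked transcripts varied between libraries within each genotype. Lyz2, a lysozyme of macrophages, had 57, 27 and 920 counts in WT replicates 1 to 3 and 73, 436 and 330 in Tlr7-/- replicates 1 to 3. C1qb had 8, 1 and 109 counts in WT and 6, 95 and 54 in Tlr7-/- libraries. Ddx3y, a gene of the Y chromosome, had 282, 493 and 0 counts in WT and 1020, 0 and 1304 in Tlr7-/- libraries. The Y-linked genes Uty, Kdm5d and Eif2s3y had at most 1 count in WT replicate 3 and 0 in Tlr7-/- replicate 2. They had 53 to 1222 in the other libraries. Libraries of each group thus differed in sex composition and did not all come from the same animals, and the comparisons were not adjusted for sex.

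Genes higher in both parts of the knockout group may be enriched for long genes, a hypothesis found and tested on the same data. Their median span was 127.9 kb, above that of all 10000 random lists matched on expression, which had a median of 29.15 kb, while genes lower in both had 9.811 kb against 27.59 kb. After removal of the trend with GC content and length the 35 higher genes had a median of 47.72 kb, at percentile 96.88 of the random lists, so part of the excess may come from a technical trend with length.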
